A study of Mus musculus with 12 samples.

How the data were processed

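RNA sequencing of mouse brain was analysed in 12 libraries, 3 in each of 4 groups given by the labels: wildtype, Notch conditional knockout, and each of these after prenatal valproic acid. Per the labels, RNA was extracted with a column kit, ribosomal RNA was depleted and libraries were made with an NEBNext Ultra kit. The authors' processing notes name HISAT2 and the mouse build GRCm39 without versions; the counting program, the annotation release and the strand setting are not given in the sources used here. The deposited table holds raw counts per Ensembl gene for 56748 genes, with no normalisation; the values were checked to be whole numbers with totals that differ between libraries. Of these genes, 22955 had no count in any library. Symbols were attached to 52073 identifiers, which hold 99.51% of the counts, from a mouse annotation on the earlier build GRCm38, so chromosomes and gene order are given and positions are not.

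Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by edgeR's filterByExpr with the 4 groups, which left 17995, and libraries were scaled by TMM factors, which ranged from 0.93 to 1.02. A model with a mean per group was fitted to all 12 libraries with edgeR's robust quasi-likelihood method (common biological coefficient of variation 0.09), and each contrast was tested two-sidedly with Benjamini-Hochberg adjustment over all tested genes at 0.05. The contrasts were valproic acid within each genotype, knockout within each treatment, the interaction, and knockout with valproic acid against untreated wildtype. Fold changes came from the fitted model. Log2 CPM values, used in the list tests and for the mean level of a list per library, had a prior count of 2. Htr3b, Gm32335 and Rbp3 had 0 to 7 counts in the lower group, and a ratio with a 95% counting interval or, at 0 counts, a lower bound against 3 counts over the group is given for them in place of a fitted fold.

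Before the data were examined, the groups, the contrasts, 33 gene lists, the rule for naming genes and the first set of other settings were fixed. The lists covered signalling and synaptic programmes, autism risk genes, markers of the cell types and regions a forebrain sample can hold, and sex-linked genes. Of these, 32 were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, and each member count was also adjusted over the list alone; sex-linked genes were left out of these tests. In each pairwise comparison the rule named the 12 largest rises and the 12 largest falls among genes past the test with a mean of at least 1 CPM and no overlap between the groups, skipping predicted and unnamed genes, and up to 4 members per list past the test. Where fewer than 10 genes passed, all were named, with the 10 smallest p-values. The Notch receptor genes, Rbpj and Htr3a were always named, and a gene named outside the rule is said to be; not every gene the rule takes is printed.

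The valproic acid effects in the genotypes were related by Pearson's r and Spearman's rho of fold changes across genes. An r of differences of mean log2 CPM was set against 100 relabellings of treatment. The share of genes moving in opposite directions was set against 12 simulations each of no effect and of the same effect in both genotypes, since the contrasts share libraries. The methods were tested on simulated data with the observed depths and fitted spread. At 2-fold, 88.1% to 91% of changed genes were recovered in the pairwise comparisons and 85.1% in the interaction, with 0 in the wrong direction. Each time 200 genes with a mean of at least 1 CPM were changed together, by 1.5-fold, 2-fold or 4-fold. Genes were drawn independently, so recovery in the real data may be lower. With an estimated correlation camera did not recover a simulated 1.2-fold change of a list, which the preset correlation did. Because the simulated genes were independent, this cannot show which correlation suits real lists, whose genes may vary together.

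The other settings fixed beforehand were size factors of DESeq2, upper-quartile factors, removal of the 20 highest genes, no count filter, a filter at 1 CPM in 3 libraries, DESeq2's Wald test, limma-voom with and without quality weights, a fit of only the libraries compared, the replicate number as a block, an absolute log2 fold change of at least 1, and each library left out in turn. Chosen after the data were seen were a sex term, leaving out both libraries without Xist, an offset for GC content and transcript length (17678 genes), DESeq2's own independent filtering, and the valproic acid effect over both genotypes. Libraries were left out with the tested genes held fixed, and DESeq2 was run without independent filtering; these settings too were settled after first values were seen. What the replicate numbers mark is not given. After removal of the group means, 1 of 18 same-number pairs correlated above 0.1 (median r 0.012, against -0.0045 for different numbers). Same-number pairs of untreated wildtype and knockout were at 0.063, 0.088 and 0.115, and their different-number pairs at -0.099 to 0.019. For 7 libraries the best match had the same number. A pairing of libraries is therefore not excluded, and the block was used only as another setting. Groups of 3 were not searched for outlying libraries. No library was left out of the main analysis.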

Results

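Gene expression was measured by RNA sequencing in 12 mouse brain libraries, which the series describes as adult forebrain. They formed 4 groups of 3 libraries: wildtype, Notch conditional knockout (labelled htr3a Notch KO), wildtype exposed before birth to valproic acid, and knockout exposed before birth to valproic acid. Valproic acid is an antiepileptic drug and histone deacetylase inhibitor, and prenatal exposure to it is used to model autism in rodents. The Notch gene removed, the driver of the deletion, the dose and the day of exposure are not given in the sources used here. Total counts per library were 18139178 to 24944681 in wildtype and 16887885 to 21840608 in knockout. They were 20279003 to 24155672 in wildtype with valproic acid and 18935991 to 22494104 in knockout with valproic acid. Genes encoded by the mitochondrial genome held 12.2% to 18.6% of the counts, with the highest share in knockout with valproic acid replicate 1. Xist, the RNA that coats the inactive X chromosome of female cells, had 12 counts in wildtype with valproic acid replicate 3 and 6 in knockout with valproic acid replicate 3, against 5919 to 10767 in each of the other libraries. The sex these counts point to was therefore unevenly spread over the valproic acid comparisons, since neither untreated group held a library lacking Xist. The labels do not say whether each library came from a separate animal, so the p-values of the gene tests below measure only the spread between these libraries. Camera's p-values with the preset correlation of 0.01 set a list's genes against all other tested genes. They do not measure the spread between libraries or between animals.

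Whether the receptor genes themselves were lower in the knockout was examined first. Notch1, Notch2, Notch3 and Notch4 encode the mouse Notch receptors, and Rbpj encodes the DNA-binding protein through which they act in the nucleus. Notch1 was at 16.6 to 20 CPM (read counts normalised to the size of the library) in wildtype and 16.4 to 17.6 CPM in knockout, and Notch2 was at 20.7 to 25.5 and 20.5 to 23.4 CPM. Notch3 lay at 7.26 to 11.7 CPM in wildtype and 9.74 to 11.9 CPM in knockout, Notch4 at 6.39 to 8.55 and 4.9 to 6.8 CPM, and Rbpj at 18.7 to 22 and 19.1 to 21.1 CPM. None of these 5 genes passed the test between knockout and wildtype (log2 fold changes -0.06 for Notch1, -0.11 for Notch2, 0.17 for Notch3, -0.29 for Notch4 and -0.02 for Rbpj, each with an edgeR adjusted p of 1). Under valproic acid the log2 fold changes were 0.18, 0.01, -0.04, 0.01 and -0.09 in the same order, and again none passed. The list of Notch target genes had a median log2 fold change of -0.04 between knockout and wildtype (camera adjusted p = 0.852) and -0.01 under valproic acid (mean 0.02, adjusted p = 0.577), where 0 of 19 passed the test and 2 were higher adjusted over the list alone. Counts per gene over bulk tissue do not show the loss of single exons, nor a loss in a small population of cells.

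Knockout was compared with wildtype without valproic acid to ask what the deletion alone changed in the adult forebrain. Genes in an unbroken stretch of chromosome 9 were higher in the knockout. They were Htr3a and Htr3b, which encode the subunits of the ionotropic serotonin receptor, Zbtb16, a zinc finger transcription factor, and Usp28, a deubiquitinating enzyme. Htr3a (ENSMUSG00000032269) was at 10.1 ± 0.616 CPM (mean ± SD, n = 3) in knockout and 4.28 ± 0.773 CPM in wildtype, 2.38-fold higher (log2 1.25 ± 0.15 SE, adjusted p = 5.34e-05). Htr3b (ENSMUSG00000008590) had 250 counts over the 3 knockout libraries and 0 over the 3 wildtype libraries, at least 91.4-fold higher against a floor of 3 counts over the group (adjusted p = 1.2e-09). Usp28 (ENSMUSG00000032267) was 2.16-fold higher (41.3 ± 3.17 against 19.2 ± 3.13 CPM, adjusted p = 2.51e-07) and Zbtb16 (ENSMUSG00000066687) 1.69-fold higher (30.9 ± 4.36 against 18.4 ± 2.83 CPM, adjusted p = 0.000977). Mzt1 (ENSMUSG00000033186), a small component of the complex that starts microtubules, lies on chromosome 14 and fell to 54.5 ± 3.53 from 114 ± 6.05 CPM (log2 -1.07 ± 0.07 SE, adjusted p = 1.2e-09). The predicted gene Gm32335 also rose, with 66 counts in knockout and 0 in wildtype (at least 24.1-fold, adjusted p = 0.000105). It overlaps Htr3a on the opposite strand, and the strand setting of the counts is not given in the sources used here, so reads of these neighbours cannot be assigned to either. The unnamed gene ENSMUSG00002076173 fell by 1.13 on the log2 scale (adjusted p = 0.0478).

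These 5 higher and 2 lower genes were all that passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment over 17995 tested genes. At an unadjusted p under 0.05 there were 563, or 3.13% of the tested genes, below the share of 0.05 expected with no change. Among the next smallest p-values, none past the test, were those of the ribosomal protein gene Rps29 (log2 0.40), the mitochondrial transfer RNA mt-Th (1.05), the organic cation transporter Slc22a2 (-1.22) and the RNA-binding protein gene Taf15 (0.29), each with an adjusted p of 1. Of the 17 tested serotonin system genes, Htr3a and Htr3b rose, and the same 2 rose when adjusted over the list alone (camera adjusted p = 0.2). Striatal neuron markers fell as a list (median log2 -0.18, 0 of 20 members past the test and 1 adjusted over the list alone, camera adjusted p = 1.87e-06, 0.941 with an estimated correlation). Their mean log2 CPM was 5.34 to 5.43 in wildtype, with knockout replicate 1 above (5.52) and replicates 2 and 3 below (5.05 and 4.94). Without knockout replicate 3, 0 lists passed camera. Nuclear genes of oxidative phosphorylation rose as a list (median log2 0.05, 0 of 65 past the test and 3 adjusted over the list alone, camera adjusted p = 0.000486, adjusted p = 0.941 with an estimated correlation). The intervals of count ratios and the count floors cover counting error only.

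**Figure D1:**
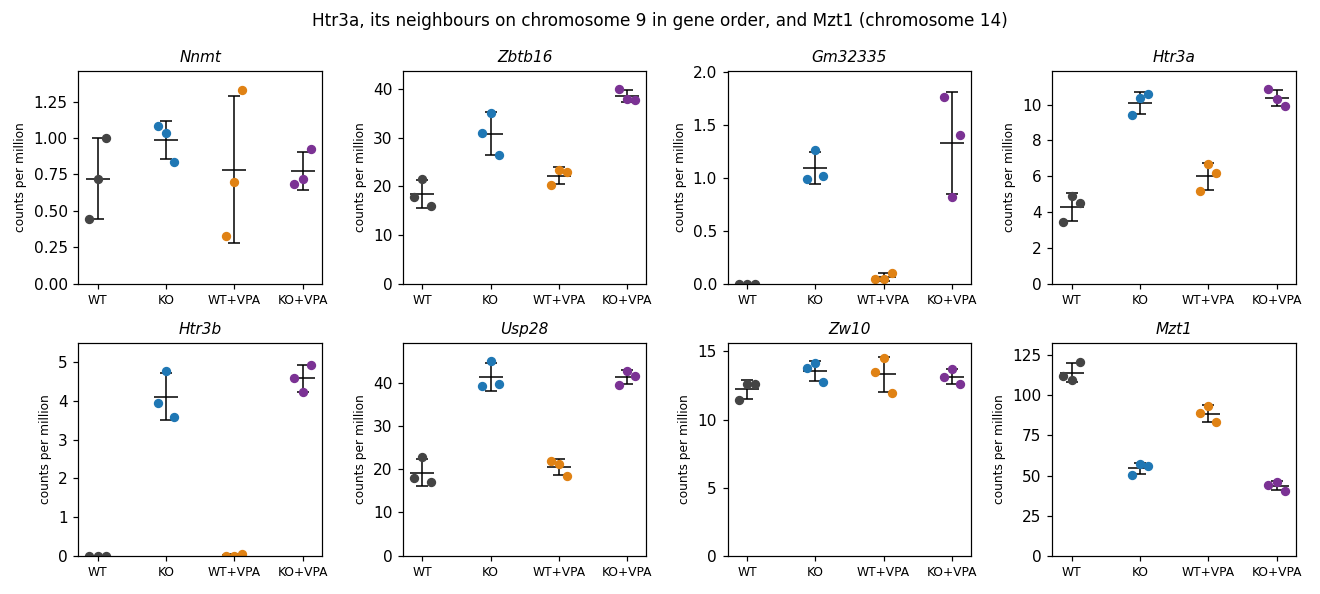
CPM of Nnmt, Zbtb16, Gm32335, Htr3a, Htr3b, Usp28 and Zw10, in their order on chromosome 9, and of Mzt1 on chromosome 14, by group; each point is a library, the horizontal bar the mean and the error bar the SD of 3 libraries. Htr3b had 0 counts in wildtype and 250 in knockout, and Mzt1 was at 109.7 to 121.1 CPM in wildtype and 40.67 to 46.13 CPM in knockout with valproic acid.

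Wildtype with and without prenatal valproic acid were compared to ask what the exposure left in the adult forebrain. Genes of striatal projection neurons were lower after valproic acid. Tac1, the precursor of substance P, was at 46.7 ± 6.5 CPM (mean ± SD, n = 3) against 86.4 ± 7.77 CPM in untreated wildtype, 1.85-fold lower (log2 -0.89 ± 0.10 SE, adjusted p = 0.000102). Drd1, the D1 dopamine receptor, was 1.77-fold lower (27.9 ± 2.71 against 49.2 ± 1.77 CPM, adjusted p = 0.00246). The striatal phosphodiesterase Pde10a was 1.68-fold lower (99.1 ± 6.49 against 167 ± 9.09 CPM, adjusted p = 0.0317). Rxrg, a retinoid receptor (log2 -0.63, adjusted p = 0.00139), and Syndig1l (log2 -0.58, adjusted p = 0.00246) also fell. All 20 tested striatal markers had negative values (median log2 -0.65), 8 fell and 19 fell when adjusted over the list alone. The camera adjusted p was 1.75e-19 with the preset correlation and 0.348 with an estimated correlation.

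**Figure D2:**
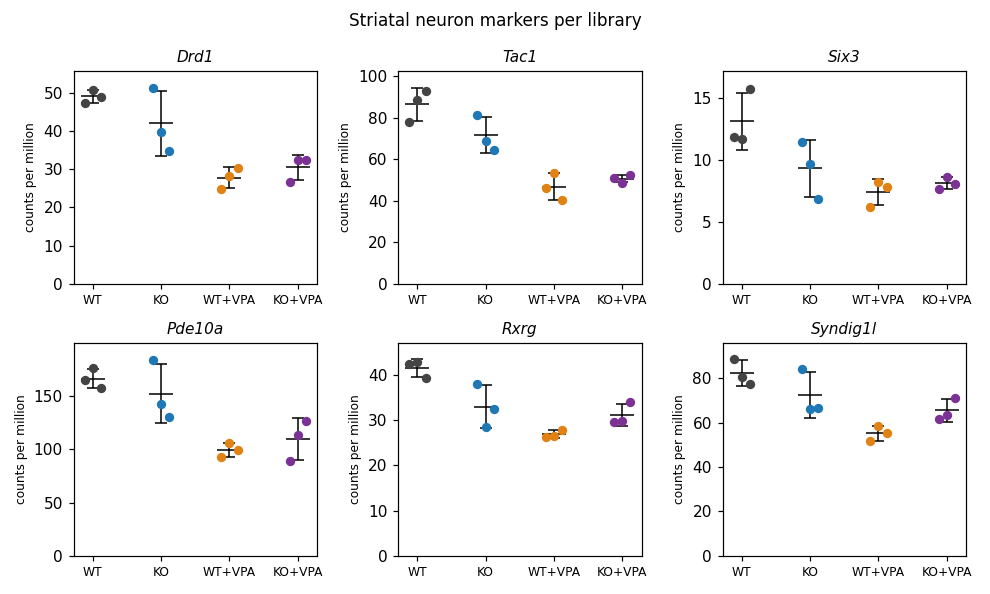
CPM of the striatal genes Drd1, Tac1, Six3, Pde10a, Rxrg and Syndig1l by group; each point is a library, the horizontal bar the mean and the error bar the SD of 3 libraries. Tac1 averaged 86.4 CPM in wildtype and 46.7 CPM in wildtype with valproic acid.

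Transcription factors of the ventral forebrain fell with them: Six3 (log2 -0.82, adjusted p = 0.017), Dlx6 (log2 -0.79, 0.0244), Meis2 (log2 -0.41, 0.0188) and Foxp2 (log2 -0.55, 0.0208), the last of these also a marker of deep cortical layers. Other genes that fell were Syt6, a synaptotagmin of deep-layer cortical neurons (1.81-fold, adjusted p = 0.000159), the kappa opioid receptor gene Oprk1 (1.66-fold), the protein kinase C gene Prkch (1.8-fold), and the transporter gene Slc35d3 (1.79-fold). So did the T-cell coreceptor gene Cd4 (1.7-fold), the small GTPase gene Rem2 (1.6-fold), the GABA-A receptor subunit gene Gabra4 (1.23-fold) and the endothelial gene Itm2a (1.3-fold). Olfactory bulb markers had a median log2 of -1.27 over 13 tested genes, of which the synaptic vesicle protein gene Synpr (log2 -0.62) and Meis2 fell, and 3 fell adjusted over the list alone (camera adjusted p = 2.02e-05, adjusted p = 0.456 with an estimated correlation). Of 65 nuclear genes of oxidative phosphorylation, the complex I genes Ndufs4, Ndufv2 and Ndufb5 fell, and 18 fell adjusted over the list alone (median log2 -0.11, camera adjusted p = 7.24e-11, adjusted p = 0.456 with an estimated correlation).

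Fewer genes rose, and the 12 largest rises of the naming rule were smaller than its 12 largest falls. The genes that rose included the potassium channel gene Kcnk9 (1.44-fold, 63.9 ± 2.69 against 44.4 ± 4 CPM), the clock gene Per1 (1.37-fold, adjusted p = 0.0123), the stress-induced inhibitor of mTOR signalling Ddit4 (1.39-fold), the netrin receptor gene Unc5d (1.39-fold) and the synaptic vesicle priming gene Unc13a (1.23-fold). The largest rise by the naming rule was Frmd6, a regulator of Hippo signalling (1.49-fold, log2 0.58 ± 0.10 SE, adjusted p = 0.00779), and Cep131, Npnt, Nwd2, Pdzrn3, Tmem132d and Cyth4 rose 1.33-fold to 1.42-fold. Immediate early genes rose as a list (21 of 26 higher, median log2 0.34, 1 past the test and 5 adjusted over the list alone, camera adjusted p = 2.02e-05), as did presynaptic vesicle genes (27 of 30 higher, 1 past the test and 3 adjusted over the list alone, camera adjusted p = 0.000409). Their adjusted p with an estimated correlation was 0.456 and 0.425. Microglia markers (17 of 20 higher, camera adjusted p = 0.00546) and Notch pathway components (23 of 34 higher, median log2 0.10, camera adjusted p = 0.0205) had 0 members past the test, with 2 and 0 adjusted over the list alone and an adjusted p of 0.348 and 0.425 with an estimated correlation.

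In this comparison 37 genes rose and 124 fell, and 2548 (14.16% of the tested genes) had an unadjusted p under 0.05. The 161 became 33 without wildtype replicate 2, 14 without wildtype replicate 3, and 36, 72 and 62 without wildtype with valproic acid replicates 1, 2 and 3. Replicate 3 of the valproic acid group lacked Xist, and without both libraries lacking it 40 genes passed, while a sex term in the fit gave 69.

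Knockout was compared with wildtype under valproic acid to ask what the deletion changed after exposure. The chromosome 9 genes were again higher: Htr3a 1.72-fold (10.4 ± 0.461 against 6.01 ± 0.753 CPM, mean ± SD, n = 3, adjusted p = 0.0243), Usp28 2.01-fold (adjusted p = 1.55e-06) and Zbtb16 1.74-fold (adjusted p = 0.000369). Htr3b had 281 counts over the 3 knockout libraries against 1, a ratio of 316 (95% counting interval 56.2 to 12500), and Gm32335 had 80 against 4 (ratio 22.5, interval 8.44 to 84.4). Mzt1 fell again, to 43.6 from 88.6 CPM (log2 -1.03 ± 0.07 SE, adjusted p = 3.75e-09). All 6 of these genes passed in both knockout comparisons in the same direction, where 0.0035 would be shared by chance. None had an interaction past the test (Mzt1 log2 0.04 ± 0.10 SE, adjusted p = 0.98; Htr3a log2 -0.46 ± 0.21 SE, adjusted p = 0.833). Rbp3, a retinoid carrier of the retina and pineal gland, had 102 counts against 7 (ratio 16.4, interval 7.66 to 41.7, adjusted p = 0.000962), and the predicted gene Gm6145 on chromosome 14 fell by 0.75 on the log2 scale (adjusted p = 0.00189).

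Choroid plexus markers, genes of the epithelium that makes cerebrospinal fluid, were higher as a list. All 16 tested members had positive values (median log2 0.62), and Cldn2, a tight junction protein of that epithelium, passed (1.91-fold, 12.5 against 6.6 CPM, adjusted p = 0.0431), with 14 past the test when adjusted over the list alone (camera adjusted p = 1.24e-15, adjusted p = 0.232 with an estimated correlation). Mfrp, a membrane protein gene of retinal pigment and ciliary epithelium, lay just outside (log2 0.96, adjusted p = 0.0607), as did the forebrain transcription cofactor gene Lmo3 (log2 -0.41, 0.0607) and the carbonic anhydrase gene Car12 (log2 0.47, 0.0756). Blood cell markers were higher in 8 of 8 (median log2 0.70, camera adjusted p = 0.000881, adjusted p = 0.274 with an estimated correlation) and meningeal fibroblast markers in 13 of 16 (median log2 0.17, camera adjusted p = 0.0113, adjusted p = 0.741 with an estimated correlation). Of these lists 0 members passed the test, and 0 and 1 did adjusted over the list alone. Ependymal markers were higher too (13 of 14, median log2 0.31, 0 past the test and 0 adjusted over the list alone, camera adjusted p = 0.000144), and cytosolic ribosomal protein genes were higher in 74 of 75 (median log2 0.21, 0 past the test and 53 adjusted over the list alone, camera adjusted p = 1.01e-30). The adjusted p with an estimated correlation was 0.45 for ependymal markers and 0.232 for ribosomal protein genes. Counts of the latter may be uncertain, since near-identical pseudogene copies can share their reads, which was not measured here. Oxidative phosphorylation genes were higher in 61 of 65 (median log2 0.16, 0 past the test and 25 adjusted over the list alone, camera adjusted p = 4.45e-18, adjusted p = 0.232 with an estimated correlation).

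Lists of autism risk, GABA receptor and synaptic genes moved the other way. Autism risk genes were lower in 44 of 50 (median log2 -0.09, 0 past the test and 2 adjusted over the list alone, camera adjusted p = 1.23e-07), and GABA receptor and chloride transport genes were lower in 19 of 21 (median log2 -0.12, 0 past the test and 0 adjusted over the list alone, camera adjusted p = 2.49e-05). Presynaptic vesicle genes were lower in 24 of 30 (camera adjusted p = 3.43e-05) and excitatory synapse genes in 27 of 40 (camera adjusted p = 0.000189), with 0 past the test and 2 and 3 adjusted over the list alone. For these 4 lists the adjusted p with an estimated correlation was 0.232. Striatal neuron markers were higher in 18 of 20 (median log2 0.14, 0 past the test and 0 adjusted over the list alone, camera adjusted p = 0.00524, adjusted p = 0.77 with an estimated correlation).

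In all, 7 genes rose and 2 fell under valproic acid, and 1338 (7.44% of the tested genes) had an unadjusted p under 0.05. Without wildtype with valproic acid replicate 3, a library lacking Xist whose choroid plexus markers were the highest of its group, 86 genes passed, and 29 passed without both libraries lacking Xist.

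**Figure D3:**
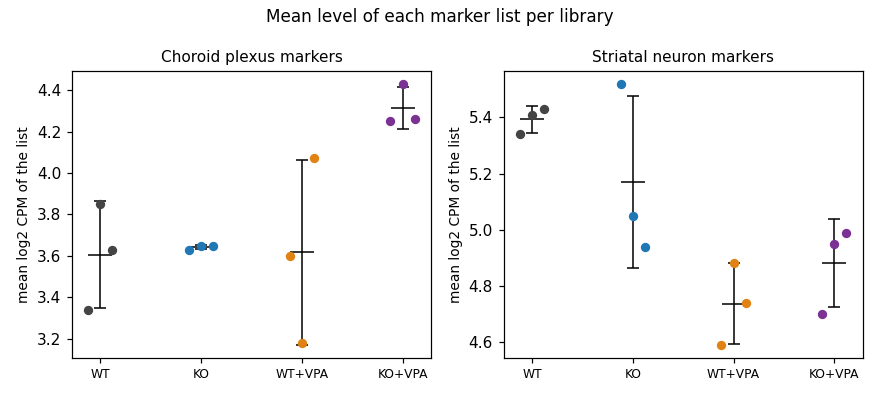
Mean log2 CPM of the choroid plexus markers and of the striatal neuron markers in each library by group; each point is a library, the horizontal bar the mean and the error bar the SD of 3 libraries. Choroid plexus markers lay at 4.25 to 4.43 in knockout with valproic acid and 3.18 to 4.07 in wildtype with valproic acid.

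Knockout with and without valproic acid were compared to ask whether the exposure acted alike in the knockout. Igfbp2, an insulin-like growth factor binding protein secreted by meninges and choroid plexus, was 1.44-fold higher after valproic acid (93.7 ± 1.87 against 64.9 ± 3.37 CPM, mean ± SD, n = 3, adjusted p = 0.00385). Slc29a4, a transporter of serotonin and other monoamines, was 1.48-fold higher (adjusted p = 0.0429). Rbp3 had 102 counts against 3 (ratio 33.4, interval 11.1 to 165, adjusted p = 0.00177); its low level puts it outside the naming rule and it was chosen after its values were seen. The 7 genes that fell were the small GTPase gene Arl15 (1.51-fold), the phosphodiesterase gene Pde7b (1.4-fold, adjusted p = 0.0195), Trim23 (1.37-fold), the neuronal phospholipid phosphatase-related gene Plppr5 (1.36-fold), the extracellular proteoglycan gene Spock3 (1.36-fold, adjusted p = 0.00838), Serpini1, which encodes the protease inhibitor neuroserpin (1.33-fold), and the lipid transfer gene Osbpl8 (1.3-fold).

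Choroid plexus and meningeal markers were higher and striatal markers lower in this comparison. Choroid plexus markers were higher in 16 of 16 (median log2 0.65, 0 past the test and 10 adjusted over the list alone, camera adjusted p = 1.55e-09) and meningeal fibroblast markers in 16 of 16 (median log2 0.37, 1 past the test and 5 adjusted over the list alone, camera adjusted p = 7.68e-06). Their adjusted p with an estimated correlation was 0.479. Striatal neuron markers were lower in 20 of 20 (median log2 -0.26, 0 past the test and 5 adjusted over the list alone, camera adjusted p = 1.3e-05, adjusted p = 0.699 with an estimated correlation). Their mean log2 CPM overlapped between the groups, at 5.52, 5.05 and 4.94 in knockout and 4.7, 4.95 and 4.99 with valproic acid. Over all lists 10 were up and 5 down by camera, and 5 and 2 without knockout replicate 1. GABA receptor and chloride transport genes were lower in 14 of 21 (0 past the test, with 7 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.00734, adjusted p = 0.479 with an estimated correlation). Mitochondrially encoded genes, whose share of counts can mark RNA quality, were higher in 13 of 13 (median log2 0.22, 0 past the test and 0 adjusted over the list alone, camera adjusted p = 0.0273, adjusted p = 0.699 with an estimated correlation). That share overlapped between the groups, at 18.62%, 14.13% and 13.53% with valproic acid and 12.2%, 14.83% and 15.19% without.

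In knockout 3 genes rose and 7 fell after valproic acid, and 2689 (14.94% of the tested genes) had an unadjusted p under 0.05. The 10 became 48 without wildtype replicate 3, 4 without knockout replicate 3, 162 without wildtype with valproic acid replicate 3, and 2 and 3 without knockout with valproic acid replicates 1 and 2. DESeq2 gave 193, limma-voom 3 and a sex term 2.

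The response to valproic acid was then set side by side in the genotypes, which share no library. Of the 161 genes that changed in wildtype, 154 (95.7%) had the same sign in knockout, as did 10 of the 10 that changed in knockout. Each valproic acid group held 1 library lacking Xist and neither untreated group held any. A sex difference could therefore by itself make signs agree. Without both of these libraries, a fit with fewer samples, 40 genes passed in wildtype, 29 of them among the 161. Spock3, Osbpl8, Trim23 and Pde7b fell in both genotypes, 4 shared falls where chance gives 0.0482. The 161 genes moved by a median of 0.39 on the log2 scale in wildtype and 0.20 in the same direction in knockout; selecting them in wildtype inflates the first value. Across all tested genes, which are not independent replicates, Pearson's r was 0.243 (jackknife SE 0.118) and Spearman's rho 0.301. For relabellings of treatment within the genotypes, r was taken from differences of mean log2 CPM, and the real labelling gave 0.266. Among 100 relabellings, 1, the real one, gave an r as high, and the highest of the others was 0.217. The r of fold changes was lower without the count filter (0.022), with limma-voom and quality weights (0.146) and without both libraries lacking Xist (0.19). No relabellings were run for these settings, so these values cannot be set against 0.217.

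**Figure D4:**
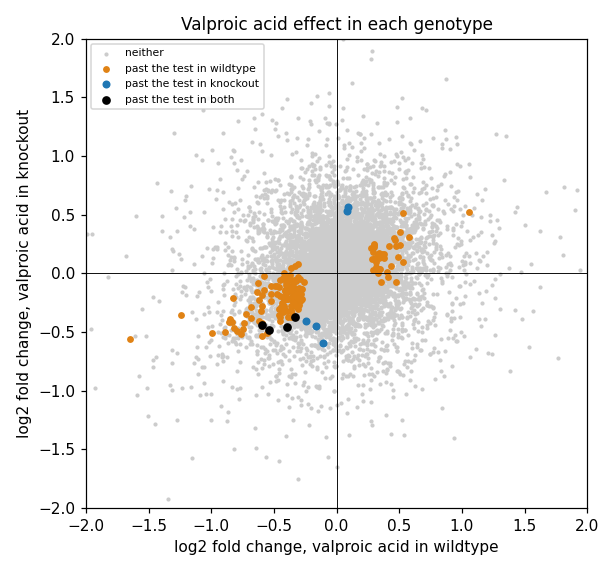
Log2 fold change after valproic acid in wildtype (horizontal axis) and in knockout (vertical axis) for each tested gene; grey points passed the test in neither, orange in wildtype, blue in knockout and black in both. Axes end at 2, which leaves out 36 genes, 2 of them past a test, and 154 of the 161 genes that passed in wildtype have the same sign in knockout.

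Whether the deletion altered the response to valproic acid was tested as an interaction. In edgeR 0 genes passed, with a smallest adjusted p of 0.833. At an unadjusted p under 0.05 there were 1075 genes, or 5.97% of those tested, near the share of 0.05 expected with no change. DESeq2, limma-voom and limma-voom with quality weights each gave 0 genes past the test. At gene level no difference between the genotypes was therefore detectable at this depth and number of libraries, where simulated interactions of 2-fold were recovered in 85.1% of genes and of 1.5-fold in 40.3%. The simulated changes were in genes with a mean of at least 1 CPM, drawn independently, so recovery in these data may be lower. Choroid plexus markers (median log2 0.64, camera adjusted p = 1.4e-08), striatal neuron markers (median log2 0.37, 2.08e-07) and ribosomal protein genes (median log2 0.19, 1.44e-15) had positive interactions as lists. Autism risk genes (median log2 -0.11, camera adjusted p = 0.000325) had a negative one. For these 4 lists the adjusted p with an estimated correlation was 0.636, and adjusted over the list alone 5 choroid plexus and 3 striatal members were higher and 2 autism risk genes lower. Without knockout replicate 1 the count was 1, without knockout with valproic acid replicate 1 it was 1, and without both libraries lacking Xist it was 4.

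The opposite question, whether the deletion moved genes changed by valproic acid back towards wildtype, used the knockout effect under valproic acid. Of the 161 genes that changed with valproic acid in wildtype, 137 (85.1%) had the opposite sign in that effect, with a median of -0.09 taken in the direction of the valproic acid change. Tac1 and Drd1, for instance, were at 46.7 and 27.9 CPM in wildtype with valproic acid and at 50.7 and 30.6 CPM in knockout with valproic acid, against 86.4 and 49.2 CPM in untreated wildtype. The wildtype libraries with valproic acid enter both effects with opposite sign, so a share above chance arises without any biology. Among as many genes of smallest p, simulated data with no effect gave 94.4% (12 simulations, 87.6% to 95.7%). Data in which valproic acid acted alike in the genotypes gave 78.6% (73.9% to 83.9%). Those data differ from the real ones, with 520 to 637 genes called for valproic acid in wildtype in place of 161. The 85.1% therefore cannot be read as a move back towards wildtype. A group of 3 libraries cannot be divided so that each effect gets its own replicated control, and 0 genes passed both tests in opposite directions.

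Knockout with valproic acid was last compared with untreated wildtype, which joins the deletion and the exposure. Genes of both knockout comparisons differed again: Mzt1 was 2.62-fold lower (43.6 ± 2.74 against 114 ± 6.05 CPM, mean ± SD, n = 3, adjusted p = 8.55e-12), Htr3b had 281 counts against 0 (at least 101-fold), and Htr3a, Usp28 and Zbtb16 were 2.43-fold, 2.16-fold and 2.1-fold higher. Tac1 (log2 -0.77, adjusted p = 0.000227), Drd1 (log2 -0.68, 0.00837), Syt6 (log2 -0.69, 0.00164), Dlx6 (log2 -0.76) and Six3 (log2 -0.70) fell as in wildtype with valproic acid. Other genes that fell were the orphan receptor gene Gpr139 (log2 -1.36), the neurokinin B receptor gene Tacr3 (log2 -1.03), the transcription factor gene Dach1 (log2 -0.80), the activin subunit gene Inhba (log2 -0.69) and the GABA-A receptor subunit genes Gabra4 and Gabra5 (log2 -0.37 and -0.38). Among the genes that rose were Tph1, which makes serotonin in the pineal gland and gut (log2 1.85 ± 0.43 SE, adjusted p = 0.0332), and mt-Th (log2 1.36). Others were the calcium channel gene Trpv4 (log2 0.87), Mfrp (log2 0.99), Steap1 (log2 0.96), S100a11 (log2 0.80), Cox6b2 (log2 0.65) and the leukocyte gene Cd37 (log2 0.62). The ribosomal protein genes Rps28 (log2 0.49, adjusted p = 0.00369) and Rps29 (log2 0.56, 0.00882) and the growth factor binding protein gene Igfbp2 (log2 0.46, 0.00369) rose as well. The receptor and ligand genes Cnr1 and Lrrtm2, the transcription factor genes Foxp1, Foxp2, Tle4 and Bcl11b, Rxrg, Synpr, the myelin gene Ermn, Rerg and BC030500 also fell (log2 -0.68 to -0.30), and Grm2, Per1, Rpl37 and Rpl37a rose (log2 0.35 to 0.43).

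As lists, striatal neuron markers were lower in 20 of 20 (median log2 -0.51, 4 past the test and 14 adjusted over the list alone, camera adjusted p = 5.86e-13) and choroid plexus markers higher in 16 of 16 (median log2 0.74, 1 past the test and 15 adjusted over the list alone, camera adjusted p = 1.74e-10). Their adjusted p with an estimated correlation was 0.376. Microglia markers were higher in 18 of 20 (median log2 0.13, 0 past the test and 0 adjusted over the list alone, camera adjusted p = 0.00261, adjusted p = 0.294 with an estimated correlation). Mitochondrially encoded genes were higher in 12 of 13 (median log2 0.27, 0 past the test and 0 adjusted over the list alone, camera adjusted p = 0.0102, adjusted p = 0.648 with an estimated correlation). Their share of counts overlapped between the groups, at 13.53% to 18.62% in knockout with valproic acid and 12.49% to 14.38% in wildtype. In total 53 genes were higher and 129 lower, and 2838 (15.77% of the tested genes) had an unadjusted p under 0.05. There were 56 genes shared with the valproic acid effect in wildtype in the same direction, 11 up and 45 down, but the untreated wildtype libraries serve both comparisons, which alone makes genes shared. The 182 genes became 115, 112 and 32 without wildtype replicates 1, 2 and 3, 370 without wildtype with valproic acid replicate 3, and 38, 117 and 59 without knockout with valproic acid replicates 1, 2 and 3. A sex term gave 45.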

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

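Every test of an explanation in this part concerns a pattern already seen in these data, and the genes compared for shared words were taken from that pattern. The tests of a gained segment, of pineal tissue, of choroid plexus tissue, and of the sex and base composition of the libraries were chosen only after the result was seen.

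Htr3a, Htr3b, Usp28, Zbtb16 and the overlapping Gm32335, which lie next to each other on chromosome 9, were higher in knockout both without and with valproic acid. Reads shared between copies are argued against by 0% of 50-base words in common between the transcripts of Htr3a, Htr3b, Usp28 and Zbtb16, and a shift of the whole chromosome by a median log2 fold change of 0.006 over its 996 other tested genes. A candidate explanation is a gained segment around Htr3a in the knockout animals, such as a transgene made from a large genomic insert, but the count of 4 risers among the 10 tested genes nearest to Htr3a restates the pattern and cannot support it; the flanking genes Nnmt (log2 0.47 and 0.03) and Zw10 (0.16 and -0.02) passed in neither comparison. A biological induction of these neighbours by loss of Notch stays open, because the labels describe no control carrying the driver alone. Mzt1 on chromosome 14 has no part in such a segment; none of its 10 nearest tested neighbours, looked at after the result was seen, passed in either comparison (log2 -0.49 to 0.28 and -0.35 to 0.08, smallest adjusted p = 0.0915), though Dach1, Klhl1, Pcdh9 and Klf12 were lower in both.

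Striatal neuron markers were lower after valproic acid in wildtype (median log2 -0.648, interval over resampled members -0.693 to -0.612). The sex of the libraries and base composition are argued against as the whole cause. The median was -0.655 (-0.733 to -0.588) without the libraries lacking Xist and -0.646 (-0.709 to -0.598) with an offset for GC content and length. Both lie past the bound of -0.324. These intervals resample genes that may vary together, so they do not cover the spread between libraries. Per library, the list's mean log2 CPM was 4.59 and 4.88 in the exposed wildtype libraries with Xist, against 5.34 to 5.43 in untreated wildtype. Less striatal tissue in the exposed libraries may account for the fall. The 7 markers shared by or belonging to the other striatal pathway, Ppp1r1b, Pde10a, Adora2a, Penk and Drd2 among them, had a mean log2 difference of -0.666. Its interval over libraries was -0.842 to -0.489, past the bound of -0.429 set from Drd1 and Tac1 (mean -0.858). Olfactory bulb markers (median log2 -1.272), hypothalamic and pituitary markers (10 of 10 lower, median log2 -0.963, camera adjusted p = 0.00546) and oligodendrocyte markers (18 of 20 lower, median log2 -0.121, camera adjusted p = 0.00285) were lower in the same libraries, each with an adjusted p of 0.456 with an estimated correlation. Lower expression in, or fewer, striatal neurons after prenatal exposure stays open, since bulk tissue gives no measure of what was dissected.

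Rbp3 and the choroid plexus markers were higher in knockout with valproic acid than in wildtype with valproic acid. Choroid plexus carried along in those libraries and a change of the choroid plexus itself cannot be told apart, since the list's median log2 of 0.618 is the pattern itself. Blood cell markers were higher in that comparison too (8 of 8, median log2 0.699, camera adjusted p = 0.000881, 0.274 with an estimated correlation). Against knockout and untreated wildtype, where choroid plexus markers were also higher, they were not (median log2 -0.09 and -0.036, 3 of 8 higher in each). After valproic acid in wildtype they were lower in 7 of 8 (median log2 -0.769, camera adjusted p = 0.0286, 0.456 with an estimated correlation). Ttr, the most abundant transcript of the choroid plexus, picked after values were seen, averaged 1570 CPM in wildtype, 1791 in knockout, 1792 in wildtype with valproic acid and 2710 in knockout with valproic acid (log2 0.60 against wildtype with valproic acid, adjusted p = 0.634). Pineal tissue in knockout with valproic acid replicates 1 and 2, where Rbp3 was highest (1.53 and 2.35 CPM, against 1.14 in replicate 3), is a candidate explanation too: 12 of 14 detected pineal genes other than Rbp3 were higher than in wildtype with valproic acid and 7 had both libraries among their highest 3, with Tph1 at 1.75 against 0.482 CPM, Tulp1 at 0.66 against 0.0613 and Pde6g at 0.793 against 0.248. Against it stand Aanat, the enzyme of melatonin synthesis, at 0.733 against 0.748 CPM, Rcvrn at 0.0919 against 0.2, Pdc with 2 counts over all libraries and Gngt1 with 0. Detected meant at least 10 counts over all libraries, and several of the 14 held few: 15 each for Lhx4 and Isl2, and 31 for Crx. The counts of 12 and 7 rest partly on such genes. Wildtype libraries held choroid plexus markers too (mean log2 CPM 3.34 to 3.85).

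Between the genotypes the response to valproic acid differed by camera's interaction test in 10 lists. The interaction median log2 was 0.636 for choroid plexus markers, 0.336 for ependymal markers, 0.257 for meningeal fibroblast markers, 0.369 for striatal neuron markers, 0.191 for cytosolic ribosomal protein genes and 0.092 for nuclear oxidative phosphorylation genes. It was -0.124 for GABA receptor and chloride transport genes, -0.118 for presynaptic vesicle genes, -0.11 for autism risk genes and -0.096 for excitatory synapse genes. With an estimated correlation none of the 10 passed (adjusted p of 0.636 or 0.71). Single genes past the test numbered 0 in edgeR, DESeq2 and limma-voom. In edgeR 1075 genes, 5.97% of those tested, had an unadjusted p under 0.05.

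The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty entered no comparison of the main analysis, though the setting without the count filter tested them. Their counts summed to 1991 in wildtype with valproic acid replicate 3 and 2260 in knockout with valproic acid replicate 3, the libraries lacking Xist. In each other library they summed to 0 to 2.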

How the results depend on the processing

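The sex term, the fits without both libraries lacking Xist, the offset for GC content and length, DESeq2's independent filtering and the filter recomputed in each fit were chosen only after results were seen. Direction was stable: no named gene changed sign past the test under any alternative run, and 6 of the 7 genes named for knockout without valproic acid passed under every setting (all but ENSMUSG00002076173), except that Zbtb16 missed the fold limit. For knockout under valproic acid Htr3b, Usp28, Zbtb16, Mzt1, Gm32335 and Rbp3 passed under every setting except DESeq2's independent filtering, which gave them no adjusted p, and, for Zbtb16, the fold limit, while Htr3a and Cldn2 did not, and Gm6145 missed it without both libraries lacking Xist (adjusted p = 0.0576, the highest over its settings). For valproic acid in wildtype Tac1, Syt6, Prkch, Drd1, Rxrg, Syndig1l and Synpr passed under every setting but the fold limit, which none of them meets, 7 of 35 named genes, and for valproic acid in knockout 0 of 9. The cause of the changes below was not tested unless stated.

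Counts of genes moved most in the valproic acid comparisons. For valproic acid in wildtype the 161 became 512 without the count filter, which tests more genes, 333 with DESeq2 (447 with its independent filtering), 537 with limma-voom and quality weights, 247 with only the libraries compared, 81 with the GC and length offset, 52 with that offset and the replicate block, 69 with a sex term, 40 without both libraries lacking Xist, which leaves fewer samples, and 4 with an absolute log2 fold change of at least 1. For valproic acid in knockout the 10 became 391 without the count filter, 193 with DESeq2 (283 with its filtering), 3 with limma-voom, 41 with only the libraries compared, 6 with the replicate block, 2 with a sex term, 3 with the GC and length offset, 3 with that offset and the block, and 1 with the fold limit. For knockout with valproic acid against untreated wildtype the 182 became 649 without the count filter, 414 with DESeq2 (517 with its filtering), 342 with only the libraries compared, 45 with a sex term, 49 with the offset, 41 with the offset and the block, and 16 with the fold limit. For knockout without valproic acid the 7 became 15 without the count filter and 11 with only the libraries compared, and upper-quartile factors gave 5 up and 1 down. For knockout under valproic acid the 9 became 60 without the filter, 25 with DESeq2, 204 with limma-voom and quality weights, 29 without both libraries lacking Xist, and 5 with the fold limit. The 0 interaction genes became 5 without the filter and 4 without both libraries lacking Xist. With the replicate block 115 genes passed for valproic acid in wildtype, 12 for knockout under valproic acid and 132 against untreated wildtype.

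Leaving out each library in turn gave 14 to 225 genes for valproic acid in wildtype, 6 to 9 for knockout, 7 to 86 for knockout under valproic acid, 2 to 162 for valproic acid in knockout, 0 to 1 for the interaction and 32 to 370 against untreated wildtype. Fits were on the same tested genes, and the group left with 2 libraries was taken to vary like the others. List tests past camera, 70 over all contrasts, were 55 to 81 in these fits, 5 with fry and 0 with an estimated correlation. Autism risk genes after valproic acid in wildtype changed sign with the GC and length offset (median log2 -0.003, adjusted p = 0.974) and with the offset and the block (-0.004, 0.965). The r of 0.243 between the genotypes became 0.022 without the count filter, which adds genes with few counts, 0.146 with limma-voom and quality weights and 0.19 without both libraries lacking Xist. It was 0.163 to 0.265 over the libraries left out, and with the filter recomputed after each library was left out it was 0.174 to 0.382, or 0.151 to 0.256 without the sex-linked genes that this filter admits. The opposed share of 85.1% was 73.1% to 95.2% over the libraries left out. DESeq2's independent filtering gave no adjusted p for 16746 of 17995 genes in knockout under valproic acid, all 9 called genes among them. At the observed depth and number of libraries and the fitted spread, a 1.5-fold change was recovered in 62.7% to 65.7% of simulated genes in pairwise comparisons. These genes had a mean of at least 1 CPM, and the share due to depth was not tested.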

Other observations

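The effect of valproic acid over both genotypes, its choice of genes and its settings were chosen only after results were seen; the splits of the planned comparisons were not.

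Averaged over wildtype and knockout, 6 libraries with valproic acid against 6 without, the exposure was followed by changes in more genes than passed in either genotype alone: 382 rose and 696 fell in edgeR. Genes of striatal neurons fell, with Tac1 at 48.7 ± 4.82 against 79 ± 11 CPM (mean ± SD, n = 6, log2 -0.69 ± 0.07 SE, edgeR adjusted p = 1.99e-05), Drd1 at log2 -0.64 (adjusted p = 0.000565) and Pde10a at log2 -0.61 (adjusted p = 0.00661), and 11 of 20 striatal markers passed (19 adjusted over the list alone, camera adjusted p = 4.75e-15, adjusted p = 0.382 with an estimated correlation). Olfactory bulb markers were lower (median log2 -0.96, 3 of 13 past the test and 3 adjusted over the list alone, camera adjusted p = 2.92e-05, adjusted p = 0.561 with an estimated correlation), as were hypothalamic and pituitary markers (median log2 -0.56, 1 of 10 and 1, camera adjusted p = 0.0428, adjusted p = 0.573 with an estimated correlation). Choroid plexus markers were higher (median log2 0.38, 1 of 16 past the test and 1 adjusted over the list alone, camera adjusted p = 8.13e-05, adjusted p = 0.561 with an estimated correlation). This came from the knockout (median log2 0.65, 16 of 16 higher), since in wildtype the list did not pass (median log2 0.06, 9 of 16 higher, camera adjusted p = 0.976). Syt6 of deep cortical layers (log2 -0.64, adjusted p = 4.32e-05), the ventral forebrain transcription factor gene Dlx6 (log2 -0.64) and the receptor genes Gpr139 (log2 -0.91) and Tacr3 (log2 -0.68) fell too. The activity-induced transcription factor gene Fos rose (log2 0.68 ± 0.14 SE, 16.1 against 10.1 CPM, adjusted p = 0.0132), as did the sulfonylurea receptor gene Abcc8 (log2 0.46) and the potassium channel gene Kcnk10 (log2 0.45). Of 26 immediate early genes 5 rose and 0 fell (10 rose and 1 fell adjusted over the list alone, median log2 0.24, camera adjusted p = 0.000167, adjusted p = 0.561 with an estimated correlation). Meningeal fibroblast markers rose in 5 of 16 (6 adjusted over the list alone, camera adjusted p = 0.000252) and oxidative phosphorylation genes fell in 13 of 65 (16 adjusted over the list alone, camera adjusted p = 2.42e-07), each with an adjusted p of 0.561 with an estimated correlation. Mitochondrially encoded genes were higher too (median log2 0.18, 0 past the test and 0 adjusted over the list alone, camera adjusted p = 0.0172, adjusted p = 0.573 with an estimated correlation). Their share of counts overlapped, at 13.44% to 18.62% with valproic acid and 12.2% to 15.19% without. With camera adjusted p under 0.05 too, Notch pathway components (0.00685), Wnt signalling (0.00623), microglia (0.00199), astrocyte (0.0142) and presynaptic vesicle genes (0.0299) leaned up. Interneuron (0.0251), oligodendrocyte (0.0251) and neurogenesis genes (0.0428) leaned down, and with an estimated correlation no list had an adjusted p below 0.382.

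A chance assignment of treatment among these libraries is argued against for that count. Among 100 of the 200 splits of treatment within the genotypes, 1, the real one, gave as many as 1078 genes, and the highest of the others gave 165. The splits take each library as a separate unit, which the labels do not state, so chance differences between animals or litters are not excluded. The libraries' sex cannot be set aside, since 298 genes passed without both libraries lacking Xist, 286 of them among the 1078 and in the same direction, and a sex term gave 172. Leaving out any other pair made of a library from each valproic acid group gave 340 to 844, so part of that loss may come from fewer samples. The GC and length offset gave 288 and, with the replicate block, 187. Without wildtype replicate 3 the count was 426, without knockout replicate 3 531, without wildtype with valproic acid replicate 3 603, and without knockout with valproic acid replicates 1 and 3 638 and 600.

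Other splits of the libraries into groups of the same sizes were counted for each planned comparison. The pairwise comparisons have 10 splits each, too few for a share under 0.05. Valproic acid in wildtype gave 161 genes and at most 4 in another split, so 1 split reached the count. Knockout gave 7 and at most 11, with 3 splits as high; knockout under valproic acid gave 9 and at most 2, with 1 split as high. Valproic acid in knockout gave 10 and at most 1, with 1 split as high, and knockout with valproic acid against untreated wildtype gave 182 and at most 0, with 1 split as high. For the interaction the real count is 0, which each of the 60 regroupings must reach, so they say nothing about chance. The highest gave 1591 genes and points to a structure of the samples: it set the 6 untreated libraries against the 6 with valproic acid.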
